A study of Mus musculus with 4 samples.

How the data were processed

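Prostate RNA from 4 groups of male mice was measured on Agilent mouse expression arrays with 1 colour, Cy3. TRAMP mice carry SV40 early genes under the rat probasin promoter, which acts in prostate epithelium, and C57BL/6 mice served as the normal counterpart. Per the labels' protocols, mice 8 weeks of age received olive oil or 600 mg/kg of a tocopherol mixture rich in gamma-tocopherol (TmT), a form of vitamin E, by gavage after a night without food. Prostates were taken 12 hours later and frozen, and each group had 3 mice. The labels give 1 array per group, 4 arrays in all, and do not state whether an array held the RNA of 1 mouse or of a pool. All 4 arrays lay on 1 slide and carried 1 scan time, so neither slide nor scan time differed between groups, while each group had its own position on the slide.

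The values started from the scanner software's processed signal, a linear intensity per spot that had been background-subtracted and detrended within the array, per the file headers. The software was Agilent Feature Extraction 10.2.1.3 with the probe positions of mouse build mm9. Its multiplicative detrending had been applied to every array except that of TRAMP mice after TmT. No normalization between arrays is recorded in the headers. The deposited value table of the series held the same intensity values, equal for all 45018 features of each array, so its scale is linear and it is not centred. Its medians were 30.2 for C57BL/6 after oil, 21.3 for C57BL/6 after TmT, 25.3 for TRAMP after oil and 13.8 for TRAMP after TmT. Flags for background, saturation and outlier spots came from the same software, per the file headers.

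Control spots and spots with a non-uniformity or population outlier mark were left out. These marks covered 131, 207, 348 and 178 spots in the order of groups just given, and no spot was saturated. Each intensity was expressed as log2 minus the log2 of its array's 75th percentile, and spots of 1 probe were averaged. A gene was the gene name in the scanner file and was represented by its brightest probe over the 4 arrays, for 27974 genes. Symbols were updated through the RefSeq accession of the probe where the reference table (assembly GRCm38) held it, which matched 24836 of 41174 probes and changed the symbol of 4058. Coordinates are those of the probes in the files, on mm9, and the exon or untranslated region under a probe was not looked up.

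Spots well above background made up 74.1% of 43379 on the array of C57BL/6 after oil, 68.1% on C57BL/6 after TmT, 70.4% on TRAMP after oil and 63.9% on TRAMP after TmT. The 75th percentiles of the processed signal were 161, 118, 139 and 71.3. Among 143 probes printed 10 times each, the median SD between spots of 1 array was 0.113, 0.109, 0.177 and 0.134 log2 units. The number of arrays limits the precision, because a spot error covers the measurement of a spot and not the difference between mice.

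Between pairs of arrays no test was possible. For these 4 comparisons the count of genes at least 2-fold different was taken among genes well above background on both arrays. Genes above background on 1 array only were counted apart, as bounds. A bound sets the brighter value against the higher of the dim probe's own value and the lowest value well above background on that array, and is written as at least N-fold. A difference printed with ± carries the scanner software's error of its spots, unless a fitted difference with its standard error is named.

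Genotype and treatment were then fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, additive model, Benjamini-Hochberg adjustment, threshold 0.05) on 19925 genes well above background on at least 2 arrays. This model leaves 1 residual degree of freedom, which is the interaction of genotype and treatment, so the interaction serves as the error. The fitted prior had 4.47 degrees of freedom and an SD of 0.355. Data were also simulated from each gene's mean over the 4 arrays with noise drawn from that prior. With 200 genes changed by genotype among 19925, the fit recovered 0% of the changes of log2 size 1, 8% of size 2, 78% of size 3 and 94% of size 4. It made 99 calls, 9 of them false. In the data 2749 genes had a genotype contrast of at least 2-fold, so the share of changed genes may differ, and recovery with it. The spread of the genotype, treatment and interaction contrasts and correlations across genes were computed over the same 19925 genes, and genes are not independent replicates.

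For 36 gene lists of cell types and pathways, the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays and is not a test. Members past the adjusted threshold were counted over all genes and adjusted over the list alone. Comparisons, lists, tests and alternatives of the main results were set before the data were examined, with the exceptions named in the closing section. The tests of explanations in that section address patterns first seen in these data.

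Genes were named by a rule set at the same time. It took the 10 highest and 10 lowest genes per comparison among those with a symbol, measured on both arrays, a difference over 2 times its spot error, and all probes of the gene on the same side of 0. It also took the 15 highest and 15 lowest genes past the threshold in the additive fit (or those that passed, if fewer), up to 4 members per list and comparison, and 18 index genes. Genes outside that rule are named as chosen after their values were seen.

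The alternatives were quantile normalization, median centring, normexp with offset 50, the deposited value table, a stricter and no background filter, the mean over all probes of a gene, 1.5-fold and 3-fold thresholds, and the limma fit with an intensity trend or with robust = TRUE. A correction for trends across the slide was added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for all other steps. Probes for the SV40 genes were not used here, so the transgene itself was not measured. Results for a few genes and for 1 gene list are not reported here.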

Results

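Expression in the mouse prostate was measured in 4 groups that crossed genotype (C57BL/6 or TRAMP, a model that develops prostate tumours) with a gavage of olive oil or TmT. Each group was represented by 1 array, so no difference between arrays had a replicate check and no p-value is given for one. All differences are log2 values after scaling to the 75th percentile, from n = 1 array per group. The labels do not give the background strain of the TRAMP mice, so the genotype differences are those between the lines and cannot be assigned to the transgene alone. Genes well above background on both arrays numbered 17251 to 18921 in the 4 comparisons.

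The first comparison asked how the prostate of TRAMP mice differed from that of C57BL/6 mice after oil alone. Proliferation genes were higher in TRAMP: Mki67, a marker of dividing cells, by 3.22 ± 0.20, the replication helicase subunit Mcm6 by 3.56 ± 0.20, the chromatin remodeller Hells by 3.89 ± 0.26 and Uhrf1, which guides DNA methylation at replication, by 3.41 ± 0.20. Of 47 measured genes of the cell cycle and E2F list, 40 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 2.02 that lay above all 10000 random lists. Several secretory products of the prostate were lower, among them Mmp7 at -5.12 ± 0.20, Ren1 (renin) at -5.05 ± 0.28, Tgm4 (the prostate transglutaminase) at -4.11 ± 0.20 and Pbsn (probasin) at -2.95 ± 0.20. Of 24 measured genes of the prostate secretory and lobe list (prostate secretory genes below), 10 were at least 2-fold lower and 3 at least 2-fold higher. Their median of -0.68 lay below all random lists. The share of each prostate lobe in a sample was not measured. In this and the other comparisons, a difference in the lobes taken was not tested and cannot be told apart for these genes.

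Markers of other cell types moved with the same pair of arrays. Adipocyte genes were higher in TRAMP after oil, with a median of 2.32 over 13 measured genes, 11 of them at least 2-fold higher, including Ucp1 at 4.18 ± 0.21 (the uncoupling protein of brown fat), Cidec at 3.50 ± 0.20, Retn at 3.06 ± 0.23 and Cfd at 2.67 ± 0.20. All 14 adipocyte genes belong to no other list, and 13 were also above background on the C57BL/6 oil array. Stromal, nerve and basal markers were lower, with medians of -0.93 for endothelium, -0.90 for Schwann cells and ganglia, -0.62 for fibroblasts, -0.71 for basal epithelium and -0.79 for skeletal muscle, all below the middle 95% of random lists. Smooth muscle lay inside it at -0.35. Examples are the fibroblast proteoglycan Dcn at -2.36 ± 0.20, the basal keratin Krt5 at -1.89 ± 0.20 and the endothelial cadherin Cdh5 at -1.34 ± 0.21. Neuroendocrine and neuronal genes had a median of -1.08 over 15 measured genes, 9 of them at least 2-fold lower, with Chga (chromogranin A) at -2.01 ± 0.22 and Syp (synaptophysin) at -1.13 ± 0.20.

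Interferon-stimulated genes had a median of 0.71 over 24 measured genes, above all random lists, and 11 were at least 2-fold higher, led by Oasl2 at 1.95 ± 0.20 and Rsad2 at 1.88 ± 0.20. Chaperone genes were lower, with medians of -0.44 for heat shock genes and -0.62 for the unfolded protein response. The C57BL/6 oil array, which also serves TmT in C57BL/6, had Hspa1a at 4.25, against 2.00 on the C57BL/6 TmT array, 0.50 on the TRAMP oil array and 1.76 on the TRAMP TmT array, and in the comparisons without it the heat shock medians were -0.18 for genotype after TmT and 0.05 for TmT in TRAMP. Hspa1a was at -3.75 ± 0.20, Hspa1b at -3.08 ± 0.23 and Hyou1 at -1.89 ± 0.20. Medians also lay below the random range for p53 targets (-0.48), hypoxia and glycolysis (-0.36), TGF-beta and Wnt signalling (-0.46), leukocytes (-0.41), erythroid genes (-0.61) and epididymal and sperm genes (-0.69). Of 9 settings, the main one and its alternatives, p53 targets, hypoxia and TGF-beta and Wnt signalling lay outside the range in 6, and heat shock and erythroid genes in 7. The deposited value table and median centring place every list as the main setting does, by construction. Here and below, counts out of 9 therefore hold fewer than 9 separate checks. Nrf2 targets, the antioxidant genes that electrophiles induce, had a median of -0.30 at percentile 2.71, just inside that range and outside it in 2 of the 9 settings. Further medians inside the range were 0.17 for DNA methylation and histone deacetylase genes, -0.11 for Nrf2 regulators, -0.03 for vitamin E and xenobiotic metabolism, -0.02 for inflammation, -0.31 for immediate-early genes, -0.17 for circadian clock genes and 0.09 for cholesterol synthesis. Others were 0.11 for PPAR targets, -0.16 each for growth factor signalling, ribosomal proteins and oxidative phosphorylation, -0.15 for seminal vesicle genes, -0.35 for urothelium, -0.09 for luminal epithelium and -0.08 for lymphocytes.

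Among named genes measured on both arrays, the lowest differences after oil were Ms4a5 at -6.85 ± 0.21 (chromosome 19, 11351133 to 11351192), Fcgbp at -5.35 ± 0.20, Mmp7 and Ren1 as given above, and then Gsdma at -4.84 ± 0.21. The highest were Scgb2b20 at 6.09 ± 0.26, the olfactory receptor gene Olfr170 at 4.80 ± 0.21, the trehalase gene Treh at 4.2 ± 0.21 and the DNA glycosylase gene Neil3 at 4.2 ± 0.25. Scgb2b20 was at -3.84 on the C57BL/6 oil array, against 0.21 on C57BL/6 after TmT, 2.24 on TRAMP after oil and 0.55 on TRAMP after TmT. Its genotype difference after TmT was 0.33. In all, 1465 genes were at least 2-fold higher and 1483 at least 2-fold lower in TRAMP, 15.6% of 18921 measured genes. This balance turned with quantile normalization (1647 higher and 1310 lower), median centring (1536 and 1390) and the mean over all probes (1389 and 1364). It also turned with the slide correction (1454 and 1350) and a 3-fold threshold (544 and 444). A further 285 higher and 525 lower were bounds, since 1 array was not well above background.

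After TmT the same genotype comparison again had proliferation genes higher in TRAMP: Mcm3 by 3.69 ± 0.21, Uhrf1 by 3.67 ± 0.21, Ccnb1 (cyclin B1) by 3.54 ± 0.22 and Mki67 by 2.29 ± 0.20. Of 40 measured cell cycle genes, 28 were at least 2-fold higher and 0 lower, with a median of 1.67 above all random lists. Prostate secretory genes had a median of -0.96 below all random lists, and 12 of 24 were at least 2-fold lower, including Ren1 at -3.96 ± 0.20, Pnliprp1 at -2.96 ± 0.22, Mmp7 at -2.59 ± 0.20 and Pbsn at -2.04 ± 0.20. Interferon-stimulated genes had a median of 0.91 with 9 of 21 at least 2-fold higher, led by Oasl2 at 2.31 ± 0.21 and Oas1a at 1.73 ± 0.23. The highest named genes were the antibody gene Igh-2 at 4.68 ± 0.20, Vsig1 at 4.25 ± 0.33, the tryptophan-degrading enzyme Ido1 at 4.07 ± 0.22 and Jchain, the joining chain of secreted antibodies, at 3.71 ± 0.23.

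The adipocyte median after TmT was -0.31 and the stromal medians were 0.41 for fibroblasts, 0.29 for smooth muscle, 0.18 for endothelium and 0.16 for Schwann cells and ganglia, the first pair of these stromal lists above the random range. PPAR targets and fatty acid genes had a median of -0.79 with 8 of 23 at least 2-fold lower, among them the fasting-induced genes Pdk4 at -2.52 ± 0.20, Angptl4 at -2.40 ± 0.22 and Cpt1a at -1.67 ± 0.06. Further medians below the random range were those of neuroendocrine genes (-0.39), skeletal muscle (-0.72), the unfolded protein response (-0.50), ribosomal proteins (-0.45) and oxidative phosphorylation (-0.41). Those above it were lymphocytes (0.69), cholesterol synthesis (0.34) and growth factor signalling (0.24). Of 9 settings, lymphocytes and growth factor signalling lay outside the range in 6, smooth muscle in 7, and neuroendocrine genes, cholesterol synthesis and oxidative phosphorylation in 8. In this comparison 1457 genes were at least 2-fold higher and 1050 at least 2-fold lower, 14.5% of 17251, with 560 higher and 163 lower as bounds. The balance of higher and lower genes turned under normexp, where 28.2% of the differing genes were higher against 58.1%.

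**Figure D1:**
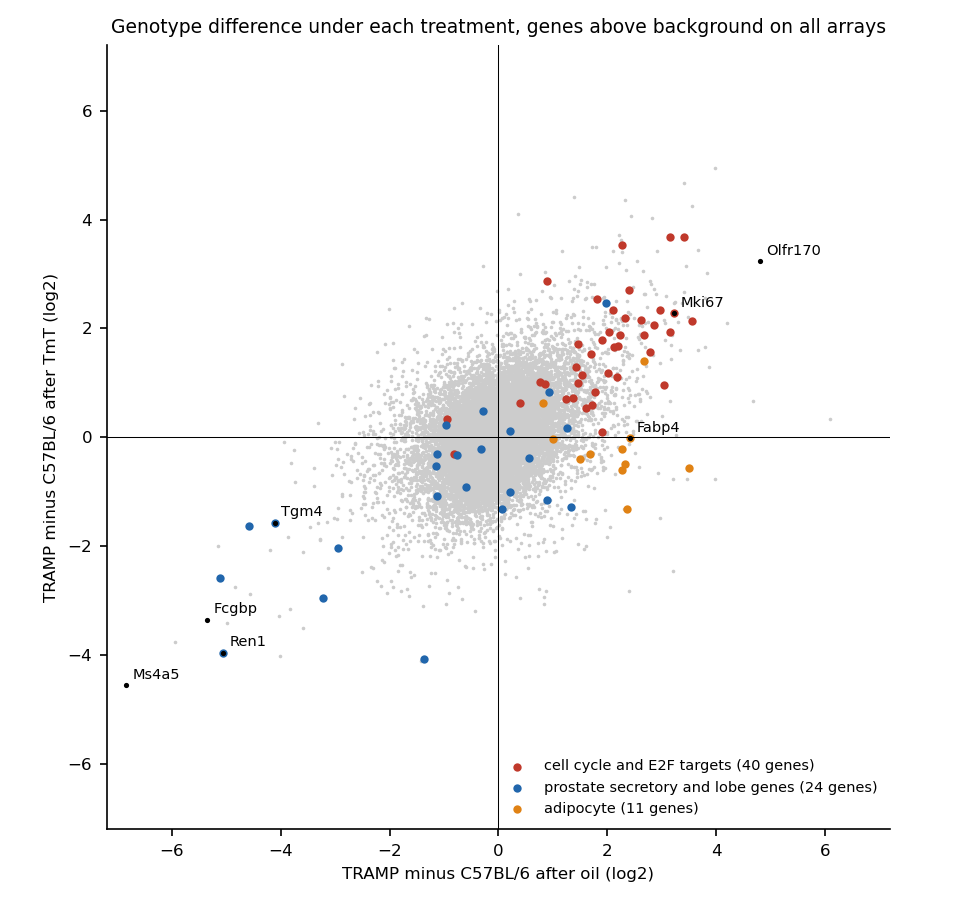
Each point is a gene well above background on all 4 arrays, with its TRAMP minus C57BL/6 difference after oil on the x axis and after TmT on the y axis (log2, 1 array per group). Most of the 40 cell cycle genes (red) lie in the upper right, prostate secretory genes (blue) lie on both sides of 0 with Ren1 in the lower left, and the 11 adipocyte genes (orange) are displaced along the x axis.

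Over both treatments, limma's additive fit found 20 genes that rose and 7 that fell in TRAMP, all at an adjusted p of 0.0488 (Benjamini-Hochberg). Those that rose included Uhrf1 by 3.54 ± 0.33 (fitted difference ± SE) on chromosome 17 at 56462657 to 56462716, Wdhd1, a replication factor, by 3.55 ± 0.32, Vsig1 by 3.90 ± 0.35 and the antibody gene Igh-VJ558 by 4.46 ± 0.38. Hells and Neil3 rose too, but were well above background on 1 C57BL/6 array only, the oil array. Others that rose were not well above background on either C57BL/6 array. Among them were Olfr167 at least 141-fold higher, Obp2a (an odorant-binding lipocalin) at least 125-fold, Olfr171 at least 49.0-fold, the kinetochore gene Knl1 at least 24.3-fold, Tcf19 at least 9.63-fold, Ercc6l at least 7.42-fold, Ahsg (fetuin A) at least 5.79-fold and the checkpoint gene Clspn at least 5.52-fold. Of the 20, 6 carry only a clone name, an accession or a provisional locus name in the files.

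**Figure D2:**
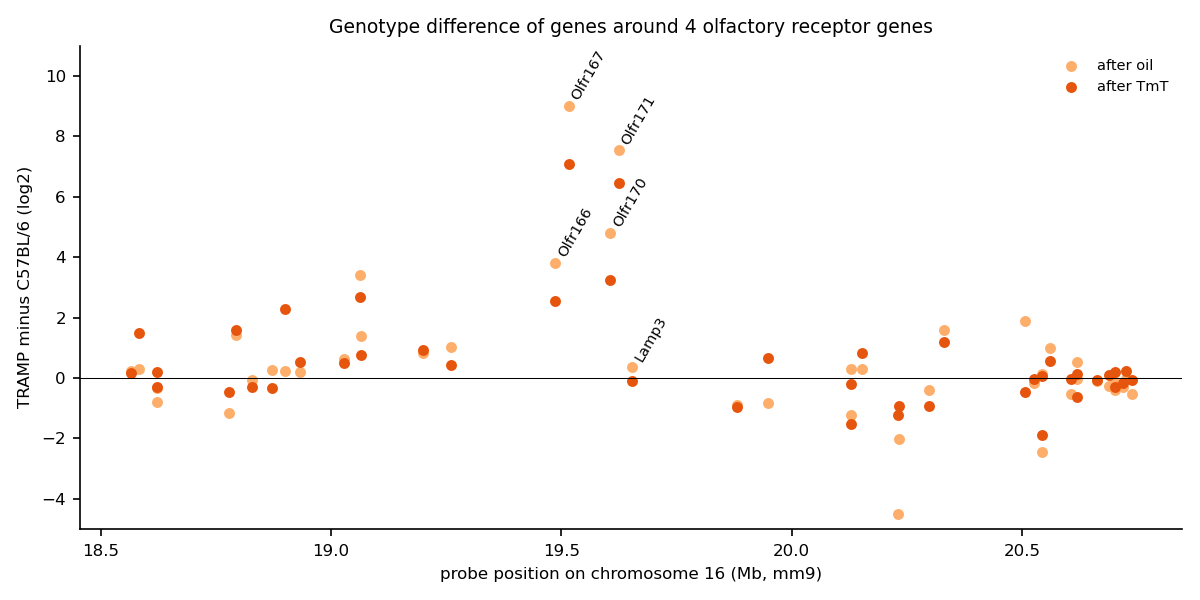
TRAMP minus C57BL/6 difference (y axis, log2, 1 array per group) of genes well above background on at least 2 arrays against the probe position on chromosome 16 (x axis, Mb, mm9), after oil and after TmT. Olfr166, Olfr167, Olfr170 and Olfr171 stand above their neighbours under both treatments, with Olfr170 at 4.80 and 3.24. Olfr167 and Olfr171 were not well above background on either C57BL/6 array, so their points rest on dim values and are not bounds.

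Of those that fell, the renin probes were well above background on all 4 arrays: Ren1 fell by 4.50 ± 0.40 (chromosome 1, 135256659 to 135256718) and Ren2 fell by 4.01 ± 0.32. These probes target near-identical genes, so their signals cannot be assigned to either gene with certainty, and C57BL/6 mice are known to carry Ren1 without Ren2, so the Ren2 probe's signal in them is not from Ren2. A strain difference between the lines at these genes was not tested. G6pc2 (chromosome 2, 69065795 to 69065854), a glucose-6-phosphatase subunit, was the lowest, at least 25.7-fold lower, with the lactate receptor gene Hcar1 at least 4.26-fold and Ceacam12 at least 2.90-fold, none of them well above background on a TRAMP array.

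By list, 2 of 48 cell cycle genes passed over all genes and 44 passed adjusted over the list alone, all higher in TRAMP. For interferon-stimulated genes the counts were 0 over all genes and 8 of 24 adjusted over the list alone, including Oasl2 at 2.13 ± 0.33 and the chemokine Cxcl9 at 1.65 ± 0.32. For prostate secretory genes they were 1 over all genes and 8 lower and 1 higher of 24 adjusted over the list alone, with Pbsn at -2.49 ± 0.38, Tgm4 at -2.84 ± 0.63 and, higher, Wfdc12 at 2.22 ± 0.34. Among DNA methylation and histone deacetylase genes, Uhrf1 passed over all genes and 3 of 21 passed adjusted over the list alone, the others being the maintenance methyltransferase Dnmt1 at 1.56 ± 0.33 and Mbd4 at 1.77 ± 0.34. Of Nrf2 targets, 0 passed over all genes and 1 of 38 adjusted over the list alone, the cystine transporter gene Slc7a11, at least 1.41-fold lower and not well above background on either TRAMP array. Slpi passed adjusted over the list alone as higher in the seminal vesicle list, where 2 genes were lower. Index genes that did not pass over all genes included Trp53, with a fitted difference of 0.29 ± 0.32, and Rb1, with 0.73 ± 0.35.

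The differences after oil and after TmT correlated across 19925 genes with Pearson's r = 0.422 and Spearman's rho = 0.370. Genes at least 2-fold higher in both numbered 483 against 104 for independent lists of that size, and 282 were lower in both against 82.0. The unadjusted p was under 0.05 for 3008 genes, where chance gives 996.25. The calls stood just under the threshold, and none passed with quantile normalization, median centring or the mean over all probes, where the lowest adjusted p was 0.0778, 0.0682 and 0.0620.

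**Figure D3:**
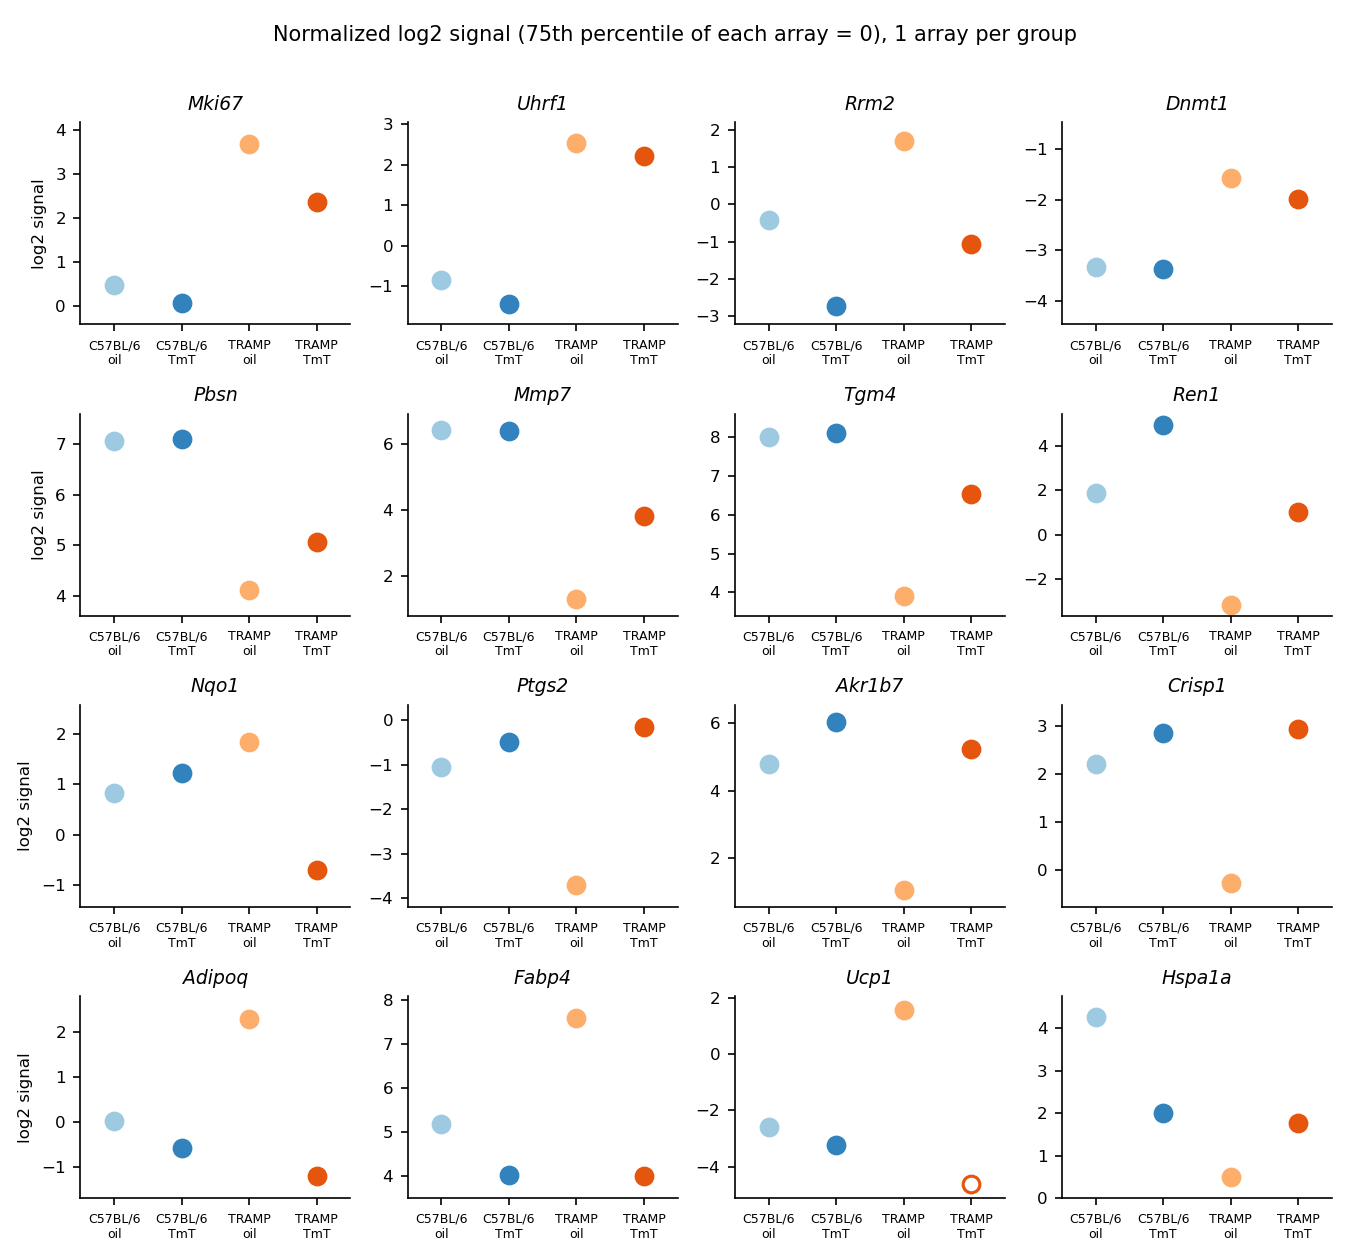
Normalized log2 signal of 16 genes on each array (x axis, 1 array per group, no error bars; the 75th percentile of an array is 0), with open circles for a signal not well above background. Mki67 and Uhrf1 are higher on both TRAMP arrays, Ren1 is lower on both TRAMP arrays and higher after TmT in each genotype, and Adipoq, Fabp4 and Ucp1 are highest on the TRAMP oil array.

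In C57BL/6 mice, the effect of the tocopherol mixture over its vehicle was examined without the transgene. After TmT, heat shock genes were lower: all 14 measured members lay below 0 with a median of -0.76, below all random lists, led by Hspa1b at -2.57 ± 0.22, Hspa1a at -2.24 ± 0.20 and the co-chaperone Dnajb1 at -1.17 ± 0.20. The heat shock median was 0.05 for TmT in TRAMP. As given above, Hspa1a was highest on the C57BL/6 oil array, so a high value on that array cannot be told apart from an effect of TmT. Renin probes were higher, Ren2 by 3.30 ± 0.20 and Ren1 by 3.07 ± 0.20, and so was Foxa2, a forkhead factor, by 2.63 ± 0.10 (chromosome 2, 147868698 to 147868757). Tex19.1 was higher by 4.07 ± 0.33 and Scgb2b20 by 4.05 ± 0.26. For TmT in TRAMP these genes went the other way, at -0.69 and -1.70. Their lowest signals were on the C57BL/6 oil array, at -4.50 and -3.84, so the differences in C57BL/6 rest on that array. The ribonucleotide reductase subunit Rrm2, needed for DNA synthesis, was at -2.30 ± 0.23, and the endotoxin receptor component Ly96 at -2.46 ± 0.21.

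Cell cycle genes had a median of -0.34 over 40 measured genes, below all random lists, with 4 at least 2-fold lower and Foxm1 higher at 1.38 ± 0.23. Markers of leukocytes and of red cells moved with this pair: the leukocyte median was -0.48, with S100a9 at -1.71 ± 0.34 and C1qa at -1.17 ± 0.21, and the erythroid median was -0.67, with Hbb-b1 at -1.16 ± 0.20. Adipocyte and stromal medians were smaller, at -0.29 for adipocytes, -0.32 for endothelium, -0.24 for fibroblasts, -0.36 for basal epithelium and -0.17 for skeletal muscle, all below the random range. Seminal vesicle genes (-0.37), cholesterol synthesis (-0.24), the unfolded protein response (-0.27) and hypoxia and glycolysis (-0.17) also lay below it, and epididymal genes (0.39) above it. Of 9 settings, epididymal genes and hypoxia lay outside the range in 6, skeletal muscle, adipocytes and endothelium in 7, and basal epithelium, fibroblasts and cholesterol synthesis in 8. Sval2 at -1.79 ± 0.22 and Slpi at -2.07 ± 0.23 led the seminal vesicle list, against Wfdc3 at 1.44 ± 0.20.

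Nrf2 targets did not stand apart in C57BL/6: their median was 0.03 at percentile 49.2 of random lists, with 0 of 38 at least 2-fold different. Nqo1 was at 0.41 ± 0.20, Hmox1 at 0.04 ± 0.20, Gclc at -0.12 ± 0.20 and Gstm1 at 0.17 ± 0.20, and the regulators Nfe2l2 (Nrf2) and Keap1 were at -0.06 ± 0.20 and 0.28 ± 0.20. The methyltransferases Dnmt1, Dnmt3a and Dnmt3b were at -0.04 ± 0.29, 0.05 ± 0.20 and -0.45 ± 0.27, and their list, with the histone deacetylases, had a median of 0.08 inside the random range, with 0 of 21 at least 2-fold lower and 3 at least 2-fold higher, among them Hdac5 at 1.65 ± 0.27 and Hdac9 at 1.49 ± 0.21. Vitamin E and xenobiotic metabolism had a median of 0.10 and inflammation one of 0.03, with Nfkbia, the NF-kB inhibitor, higher by 1.45 ± 0.21. In all, 582 genes were at least 2-fold higher and 490 at least 2-fold lower, 5.74% of 18665, with 180 higher and 311 lower as bounds. The balance turned with no background filter (1372 higher and 1871 lower) and with the mean over all probes (518 and 521).

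In TRAMP mice, the question was the effect of TmT on a prostate with the transgene. Cell cycle genes were lower after TmT, with a median of -0.73 below all random lists, 17 of 47 at least 2-fold lower and 0 higher. Cell-type markers also differed between these arrays, as given below. Whether the mix of cells contributed to the cell cycle difference was not tested and cannot be told apart from an effect of TmT. Rrm2 was at -2.76 ± 0.21, its partner Rrm1 at -1.60 ± 0.20, Kif20a at -1.48 ± 0.21 and Mki67 at -1.33 ± 0.20. Ren1 was higher by 4.17 ± 0.28, Ren2 by 3.30 ± 0.23, the aldo-keto reductase gene Akr1b7 by 4.2 ± 0.20 (chromosome 6, 34372905 to 34372964), the costimulatory ligand gene Icosl by 4.15 ± 0.22 and Ptgs2 (cyclooxygenase 2) by 3.54 ± 0.16. Akr1b7 is on the list of epididymal and sperm genes, which had a median of 0.51 inside the random range with 3 of 8 at least 2-fold higher and 0 lower, the others being Crisp1 at 3.21 ± 0.20 and Prm2 at 1.25 ± 0.21. Akr1b7, Ptgs2 and Crisp1 had their lowest signals on the TRAMP oil array, at 1.03, -3.70 and -0.28. Their genotype differences after TmT were -0.82, 0.34 and 0.09. For these genes a low value on that array cannot be told apart from an effect of TmT. Nqo1, a quinone reductase of the Nrf2 set, was at -2.55 ± 0.18. The secretory genes Tgm4 and Pnliprp1 were higher by 2.65 ± 0.20 and 2.19 ± 0.28, and the prostate list as a whole had a median of 0.13 inside the random range, with 6 of 24 at least 2-fold higher and 5 at least 2-fold lower. Apof at -1.45 ± 0.20 and Crabp1 at -1.26 ± 0.21 were among the lower ones, named after their values were seen.

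The list median largest in size was that of adipocyte genes, as for genotype after oil, which shares the TRAMP oil array with this comparison. It was -2.10, below all random lists, with 10 of 11 genes at least 2-fold lower. Among them were Fabp4 at -3.59 ± 0.20, Scd1 at -3.57 ± 0.20, Adipoq (adiponectin) at -3.49 ± 0.21 (chromosome 16, 23157576 to 23157635) and Cidec at -3.37 ± 0.20. PPAR targets and fatty acid genes, none of which is on the adipocyte list, had a median of -0.90 with 10 of 23 at least 2-fold lower, including Angptl4 at -3.30 ± 0.18 and Cd36 at -2.10 ± 0.20. That median went inside the random range with normexp (-0.19) and with the slide correction (-0.15). Stromal, nerve and basal markers were higher, with medians of 0.87 for endothelium, 0.87 for Schwann cells and ganglia, 0.62 for smooth muscle, 0.59 for fibroblasts, 0.62 for basal epithelium and 0.77 for neuroendocrine genes. Sparc was higher by 1.86 ± 0.20, Krt5 by 1.43 ± 0.20, Flt1 by 1.40 ± 0.21 and Acta2 by 1.31 ± 0.20. The seminal vesicle median was -0.33, led by Sva at -3.62 ± 0.20, and turned to 0.34 with the mean over all probes of a gene, and it lay outside the range in 5 of 9 settings.

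Nrf2 targets in TRAMP had a median of -0.01 at percentile 30.1, with 2 of 36 at least 2-fold higher and 3 at least 2-fold lower. Beside Nqo1, Me1 was at -1.70 ± 0.21, Prdx6 at -1.57 ± 0.20 and Hmox1 at -0.72 ± 0.20, against Gstm1 at 1.07 ± 0.20 and Gclc at 0.16 ± 0.20. Nfe2l2 was at -0.49 ± 0.20 and Keap1 at 0.35 ± 0.20. Dnmt1, Dnmt3a and Dnmt3b were at -0.41 ± 0.23, 0.15 ± 0.20 and -0.06 ± 0.25. Their list had a median of -0.06 inside the random range, with 0 of 21 at least 2-fold higher and 1 lower, Hdac2 at -1.77 ± 0.18. Medians inside the random range were also those of inflammation (0.25), vitamin E and xenobiotic metabolism (-0.17), immediate-early genes (0.34, outside in 2 of 9 settings), ribosomal proteins (-0.15, outside in 4 of 9), circadian clock genes (0.39), heat shock (0.05) and interferon-stimulated genes (0.01). In all, 1512 genes were at least 2-fold higher and 848 at least 2-fold lower, 13.5% of 17465, with 333 higher and 125 lower as bounds.

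**Figure D4:**
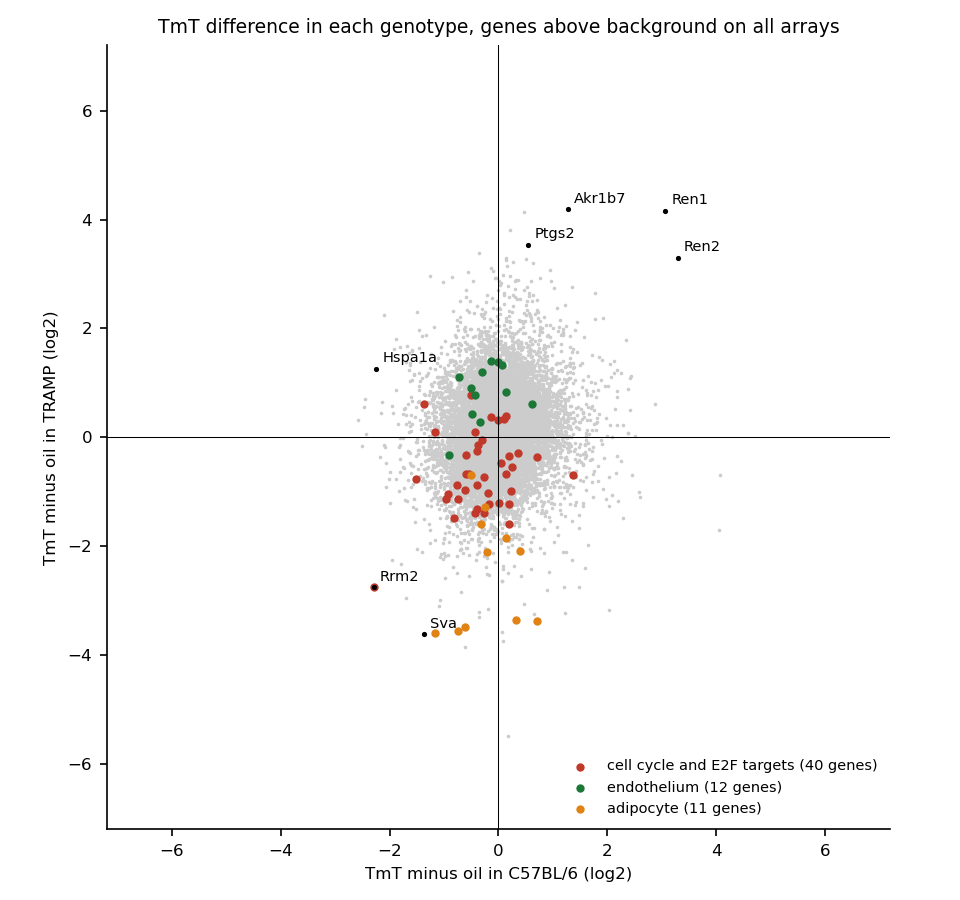
Each point is a gene well above background on all 4 arrays, with its TmT minus oil difference in C57BL/6 on the x axis and in TRAMP on the y axis (log2, 1 array per group). Ren1 and Ren2 are high on both axes and Rrm2 low on both, while adipocyte genes (orange) and endothelial genes (green) are displaced mainly along the y axis.

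Over both genotypes, 0 genes passed the adjusted threshold for TmT in limma's additive fit, where the lowest adjusted p was 0.773. The unadjusted p was under 0.05 for 1248 of 19925 genes against 996.25 by chance, and the count of genes that passed was 337 with normexp, 2 with an intensity trend and 0 with the robust fit. Adjusted over the list alone, the genes that passed were Ren1 at 3.62 ± 0.40 and Pnliprp1 at 2.06 ± 0.33 in the prostate list, and Foxa2 in the neuroendocrine list, which was not well above background on the TRAMP oil array. Rrm2 at -2.53 ± 0.34 passed likewise in the cell cycle list, with Kif11 and Cdk1, which were not well above background on the C57BL/6 TmT array. In the seminal vesicle list they were Sva at -2.49 ± 0.58, Sval2 at -2.06 ± 0.34, Svs1 at -1.55 ± 0.42 and Wfdc3 at 1.78 ± 0.35. None of these lists had a gene that passed over all genes for TmT.

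The treatment effects in both genotypes correlated across genes with r = 0.104 and rho = 0.130, and with r = 0.331 and rho = 0.363 under normexp. Genes at least 2-fold higher in both numbered 85 against 39.2 for independent lists, and 49 were lower in both against 21.0. Genes that went opposite ways numbered 38 and 53, against 22.7 and 36.3. The treatment contrast spread over genes with an SD of 0.533, close to the 0.481 of the interaction that served as its error, and the genotype contrast with 0.755.

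Whether TmT moved expression in TRAMP toward C57BL/6 was asked by setting its effect in TRAMP against the genotype difference over both treatments, which gave r = -0.08 and rho = -0.02 across genes. Against the genotype difference after oil r was -0.483, but these differences share the TRAMP oil array, and simulated arrays with no effect gave -0.501. The covariance was -0.343 against -0.229 in those simulations. The simulated arrays had no genotype difference and equal noise, while the TRAMP oil array had the widest spot SD, 0.177. The gap in covariance therefore cannot show whether TmT moved expression toward C57BL/6. Mki67 was 3.22 ± 0.20 above C57BL/6 after oil and 2.29 ± 0.20 after TmT and Ren1 went from -5.05 ± 0.28 to -3.96 ± 0.20. Nqo1 went from 1.03 ± 0.18, which became -0.04 under normexp, to -1.93 ± 0.21.

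Across the 36 lists and 4 comparisons, 57 of 144 medians lay outside the middle 95% of random lists, where 7.2 would fall by the definition of that range if members moved independently. They numbered 14 for TmT in C57BL/6, 10 for TmT in TRAMP, 19 for genotype after oil and 14 for genotype after TmT. The 22 medians inside the range for TmT in C57BL/6 lay between -0.14 for lymphocytes and 0.27 for neuroendocrine genes (outside in 3 of 9 settings), among them 0.18 for prostate secretory genes, 0.06 for smooth muscle and -0.12 for growth factor signalling.

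**Figure D5:**
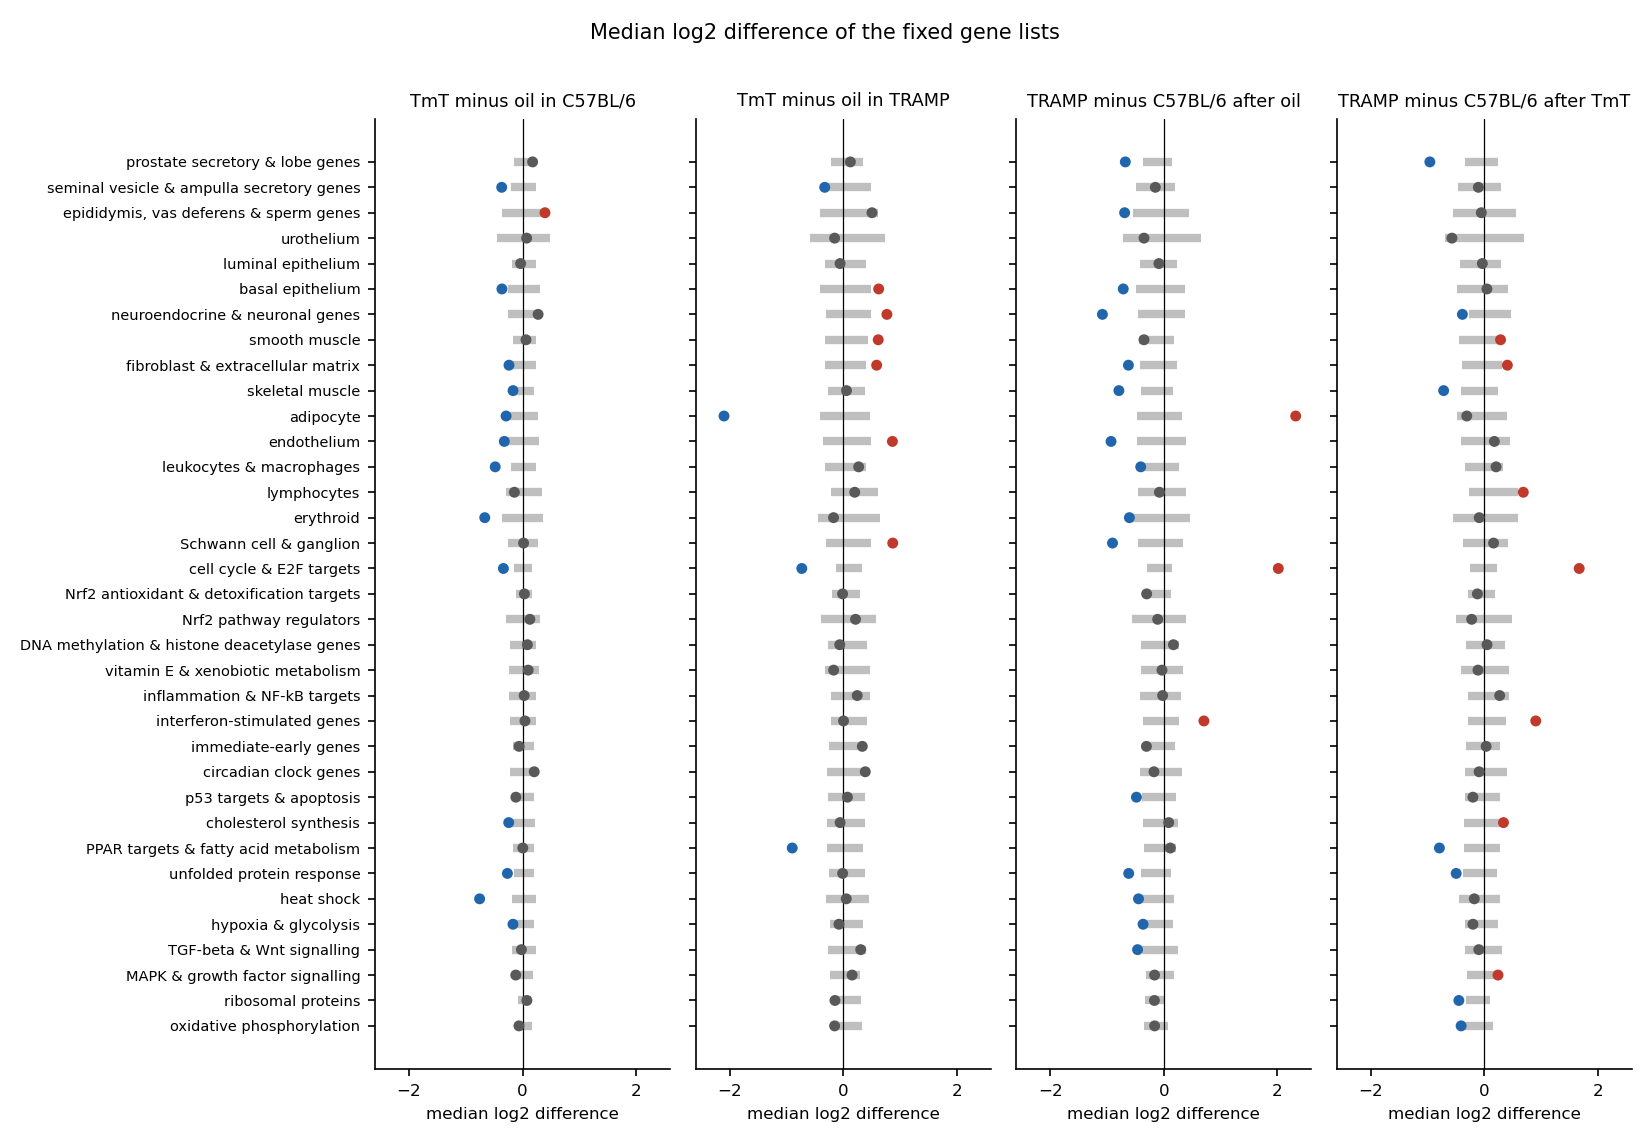
Median log2 difference of the gene lists reported here (points) in the 4 comparisons, with grey bars for the middle 95% of 10000 random lists matched on expression and red or blue points above or below them. The cell cycle list stands at 2.02 and 1.67 in the genotype panels, and the adipocyte list at 2.32 after oil and -2.10 for TmT in TRAMP.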

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

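The tests in this part address patterns first seen in these data. Those of a TmT effect on adipocyte genes, of a smaller share of stroma and nerve and of a blemish on the slide were chosen only after the test's own result was seen. The correction for trends across the slide was added after seeing the data.

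Several cell-type lists moved in opposite ways under TmT in the genotypes, and these differences were not tested because each group had 1 array. The basal epithelium median was -0.36 for TmT in C57BL/6 and 0.62 in TRAMP, a difference of 0.99. The fibroblast median was -0.24 and 0.59, a difference of 0.83. The endothelium median was -0.32 and 0.87, a difference of 1.19. The fibroblast list also had a genotype median of -0.62 after oil and 0.41 after TmT, a difference of 1.03 that was likewise not tested. Outside the gene probes, a pair of spike-in control probes, 32 spots each, lay at 0.17 relative to the 75th percentile on the TRAMP oil array and at 0.96 on average on the other 3 arrays, a difference of -0.79. Those arrays were at 1.03 for C57BL/6 after oil, 1.15 for C57BL/6 after TmT and 0.71 for TRAMP after TmT. The spots of 1 of these probes had an SD of 1.22 on the C57BL/6 TmT array.

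Adipocyte genes were higher on the TRAMP oil array than on the C57BL/6 oil array, by a median of 2.32 over 13 genes, and TmT minus oil in TRAMP was -3.59 for Fabp4 and -3.49 for Adipoq. The trend removed by the slide correction lay between -0.53 and 0.53 on the TRAMP oil array and between -0.11 and 0.42 on the C57BL/6 oil array. A trend of that size as the whole cause is argued against by its being smaller than the median. The median of 2.20 after the correction adds nothing, since a correction of that size could not have removed it. Adipose tissue collected with that sample stays open. Of 18 further adipocyte genes, the 14 well above background on the TRAMP oil array were kept, a filter that can raise their median. They stood a median of 0.87 above the other 3 arrays (0.85 with dim spots raised to the lowest level well above background), 12 of them above 0. This median lay between the values set for and against that explanation. Of the 14, 11 were well above background on all arrays. Among the 14, Dgat2 (1.95) was higher while Slc2a4 (-0.63) was not. A TmT effect on adipocyte genes may also be involved and cannot be told apart from a difference between animals with 1 array per group; the TmT median was -0.29 in C57BL/6 mice against -2.10 in TRAMP.

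Stromal and nerve genes were lower on the same array, and TmT minus oil in TRAMP had a median of 0.81 over 57 measured genes of the smooth muscle, fibroblast, endothelium and Schwann cell lists. The trend removed by the slide correction varied over the slide with an SD of 0.15 on the TRAMP oil array and 0.11 on the TRAMP TmT array. A trend as the whole cause is argued against by this size, small against the median of 0.81. The median of 0.71 after the correction adds little, since a correction of that size could hardly have removed it. Misread dim spots are argued against by a median of 0.79 over the 44 brighter members. A smaller share of stroma and nerve in that sample stays open: all 4 lists lay below the mean of the other 3 arrays, from -0.56 (smooth muscle) to -0.87 (endothelium), but these values restate what prompted the test. Adipocyte genes, also of stromal origin, went the other way. A difference between mice or in the piece of tissue taken, and an effect of TmT, stay open as untested.

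Olfr166, Olfr167, Olfr170 and Olfr171, neighbours on chromosome 16 between 19487305 and 19625194 (mm9), were all higher in TRAMP, with Olfr166 at 3.80 after oil and 2.56 after TmT, while the neighbouring gene Lamp3 was at 0.35 and -0.10. A shift of all olfactory receptor probes is argued against by a median of -0.25 over 374 other olfactory receptor genes. A blemish is argued against by a distance of at least 18 spots between spots of different genes, and 1 short sequence bound by all 4 probes by a longest shared stretch of 7 bases. A scan of the genome in windows had 6 of 15 genes higher in the window of these 4, not beyond the highest of 8 in shuffled positions. A local difference of the TRAMP genome or strain background, or a long transcript covering all 4 probes, was not tested and stays open.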

How the results depend on the processing

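The correction for trends across the slide was chosen after seeing the data, and the tolerances for calling a count (1.5 times), a correlation (0.1) or a ratio (1.25 times) moved were set before these values were seen. Of the summary values under the alternatives, 74 stayed within them and 27 moved. With normexp, genes at least 2-fold different numbered 179 for TmT in C57BL/6, 918 for TmT in TRAMP, 1133 for genotype after oil and 766 for genotype after TmT. The share of them that was higher went from 54.3% to 69.3% for TmT in C57BL/6, from 49.7% to 39.5% for genotype after oil and from 58.1% to 28.2% for genotype after TmT, and the genotype median of all genes after oil shifted by 0.11. The offset of 50 is large against the 75th percentiles of the arrays, so this setting compresses dim genes by construction, and unequally between arrays. In the same order, no background filter gave 3243, 6278, 5747 and 5390 genes, a 1.5-fold threshold 3885, 6255, 6935 and 6363, and a 3-fold threshold 213, 594, 988 and 638, since these settings admit more or fewer genes by construction.

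The 27 genotype calls of the additive fit became 0 with quantile normalization, 0 with median centring and 0 with the mean over all probes of a gene. They became 1384 with normexp (18 of the 27 among them), 278 over genes above background on all 4 arrays (7 among them), 142 with the slide correction and 371 with an intensity trend (all 27 among them in both). Without a background filter the count was 39, and the deposited value table and the robust fit gave 27. The lowest adjusted p ranged up to 0.0778. The cause was not tested, apart from the smaller set of genes above background on all arrays. For TmT, 0 calls became 337 with normexp and 2 with an intensity trend.

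The correlation of the TmT effects between genotypes was 0.331 with normexp against 0.104. The correlation of the TmT effect in TRAMP with the genotype difference was -0.483 with the difference after oil alone, which shares an array with it. Nqo1 for genotype after oil reversed to -0.038 with normexp, and the seminal vesicle median for TmT in TRAMP reversed to 0.34 with the mean over all probes. Of 1187 values of named genes under the alternatives, 975 stayed the same, 173 moved in size, 35 dropped under and 3 passed a threshold, and 1 reversed. Of 1008 list medians, 946 kept their place, 39 entered and 22 left the random range, and 1 reversed. The deposited value table changed none of these values and median centring moved no list, both by construction. The stricter background filter reuses the main values of named genes. These settings add to the counts of unchanged values without checking them. No paired analysis was possible because each group had 1 array and the labels carry no replicate numbers, and leaving out any array leaves 0 residual degrees of freedom. Signal limits the array of TRAMP after TmT most, with 63.9% of spots well above background.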

Other observations

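The gene groups in this part were chosen after their values were seen. Antibody genes were higher in TRAMP: 69 immunoglobulin chain genes had a genotype median of 0.70 after oil, with 26 at least 2-fold higher and 4 lower, and of 1.25 after TmT, with 41 at least 2-fold higher and 1 lower. For TmT minus oil their median was -0.03 in C57BL/6 and 0.78 in TRAMP. A scan of the genome in windows of 1000000 bases counted genes at least 2-fold higher in TRAMP under both treatments. On chromosome 12 between 116357929 and 117297524 (mm9), 16 of 21 scanned genes met this, against at most 8 in any window of 100 shuffles of gene positions. This window lies in the neighbourhood of antibody genes, so the scan is not support apart from the medians above. Many antibody probes share sequence, so these genes are not separate measurements. Shuffled positions do not keep such neighbours together, so a window of them can exceed 8 for that reason. Of the 69, 50 were well above background on all 4 arrays, and with dim spots raised to the lowest level well above background the genotype medians were 0.56 after oil and 1.25 after TmT, with 15 genes in that window. The labels do not give the background strain of the TRAMP mice, and a strain difference at these loci was not tested.

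Some genes outside the lists were at least 2-fold different under TmT in the same direction in both genotypes. Cited1, a transcriptional coactivator, was higher by 1.76 ± 0.21 in C57BL/6 and by 2.64 ± 0.21 in TRAMP, Sst, the hormone somatostatin, by 1.54 ± 0.07 and 1.37 ± 0.10, and Trim3 by 1.77 ± 0.21 and 2.18 ± 0.18. Nfkbia, from the inflammation list, was higher by 1.45 ± 0.21 and 1.56 ± 0.17. The interferon-induced gene Ifi27l2a was at -1.37 ± 0.21 and -1.49 ± 0.21.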
